A study of Mus musculus with 42 samples.

How the data were processed

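The samples were GFP-positive viable MLL-AF9 leukaemia cells sorted from the bone marrow of 21 mice, with 1 mRNA library and 1 ribosome footprint library per mouse, 42 libraries in all. Per the labels, male recipients aged 8 to 10 weeks received the leukaemia cells by vein without preconditioning. Cytarabine was given at 100 mg/kg daily for 5 days and doxorubicin at 3 mg/kg daily on the first 3 days, or vehicle. Bone marrow was crushed in cold buffer, red cells were lysed for 5 min on ice, and cells were sorted into a collector held at 4 °C. Cells were lysed with cycloheximide, which holds ribosomes on mRNA. A volume of 2 µl of lysate went into the Smart-seq2 mRNA library, and the rest was digested with RNase I and spun through a sucrose cushion for the footprint library.

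The deposited tables hold whole-number counts per gene for each library, per the labels and the values, with no normalization. The submitters' processing notes name cutadapt, Bowtie2, STAR, SAMtools and featureCounts and the mouse build GRCm38 (mm10). Their versions, their roles, the gene annotation and the strand setting are not given in the sources used here. Without a stated strand, reads of overlapping and antisense genes cannot be told apart. The tables held 55487 gene identifiers, of which 55141 (99.4%) matched a symbol in a gene name table.

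Groups were taken from the labels: amino acid diet with vehicle (5 mice), amino acid diet with 5+3 (4), BCAA-free diet with vehicle (5) and BCAA-free diet with 5+3 (7). The mice of the amino acid vehicle group have names with a suffix B that no other group has and that the labels do not explain. If it marks a batch, that batch cannot be told apart from the group. All 47 pairs of libraries within a group differed by more than sampling noise in each kind, as the chi-square per degree of freedom was 37.9 to 646 in mRNA and 4.12 to 25.2 in footprints. Total counts were 30996200 to 70437713 in mRNA and 2697092 to 8863472 in footprints. Of the 21 mice, 18 had an mRNA library whose deviations from its group mean matched the footprint library of the same mouse best (median r = 0.119 across genes).

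Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, libraries were scaled by TMM, and the robust quasi-likelihood test was applied to 21114 genes in mRNA and 15723 in footprints. All 4 groups entered 1 fit per kind of library, so that they shared an estimate of the spread. The 5 comparisons were 5+3 against vehicle on each diet, the BCAA-free against the amino acid diet under each treatment, and the interaction of diet with chemotherapy. Translational efficiency was tested over all 42 libraries as the interaction of library kind with group, with the mouse as a block and TMM within each kind, on 12097 genes that passed the filter in both kinds. This gave 15 results. Adjusted p is by the Benjamini-Hochberg method, and genes passed under 0.05. The tests, groups, gene lists, rule for named genes and most alternatives were fixed before the data were examined.

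Gene lists, 38 of pathways and 10 of markers of other cell types, were tested with camera in limma 3.58.1 with a preset correlation between genes of 0.01 and again with a correlation estimated per list, where at least 5 members were measured. Of 240 list tests in mRNA 96 passed, of 210 in footprints 98 and of 210 in translational efficiency 45. With an estimated correlation 10, 5 and 1 passed. Named genes were the 6 highest and 6 lowest log2 changes of each comparison among genes past the threshold. They needed a mean of at least 10 CPM in the compared groups, a symbol other than Gm with a number or one ending in Rik, no pseudogene, immunoglobulin or T cell receptor segment, and at least 75% of pairs of mice going the same way. For translational efficiency the mean was the lower of those in mRNA and in footprints over all mice. For the interaction the mean was over all mice and the rule on pairs was not applied. Up to 4 members with the smallest adjusted p were added from each list described, and a panel of 15 genes was given for every comparison: Bcat1, Bcat2, Bckdha, Atf4, Asns, Ddit3, Chac1, Sesn2, Slc7a5, Cdkn1a, Mdm2, Myc, Hoxa9, Meis1 and Mki67. Genes named outside this rule were chosen after their values were seen.

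The edgeR test was tested on simulated counts with 200 changed genes, drawn from the means and library sizes of the real data. In mRNA it recovered 37.9% of 4-fold changes for chemotherapy on the amino acid diet (20175 genes) and 50% for the diets under 5+3 (20158 genes). In footprints it recovered 93.9% (15485 genes) and 90.9% (15525 genes) of them, and for translational efficiency 54.3% (11822 genes) and 52.1% (11841 genes). For the interaction it recovered 25.8% in mRNA, 80.3% in footprints and 8.33% in translational efficiency. Of the simulated calls 14.3% for the interaction in mRNA, 7.55% for it in footprints and 7.14% for chemotherapy on the BCAA-free diet in mRNA were of unchanged genes, and 0% to 5.52% in the other results. Of 20 random lists per comparison camera with the preset correlation called 0. The simulated counts were drawn independently for each gene, so this does not test lists of correlated genes.

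Alternatives were DESeq2 1.42.0, limma voom with library weights, median-ratio scaling, one scaling over both kinds of library, no filter on low counts, only the compared groups in the fit, the replicate number as a block, no mouse block for translational efficiency, an estimated correlation for lists, and leaving out each mouse. Chosen after seeing the data were protein-coding rows only, the 4 mRNA libraries below -50 on component 1 left out, and the 2 shallowest footprint libraries left out. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. No genome sequence was used. Genome positions and gene biotypes came from a RefSeq gene table of GRCm38, the build named in the submitters' processing notes, matched by current or older symbol. The deposited tables give Ensembl identifiers and counts alone.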

Results

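The study asked how a diet without branched-chain amino acids changes gene expression and translation in leukaemia cells after chemotherapy. Mice carried MLL-AF9 acute myeloid leukaemia, a transplantable mouse leukaemia driven by a fusion of the Mll and Af9 genes, whose cells express green fluorescent protein (GFP). They ate a standard amino acid diet or a diet free of the branched-chain amino acids (BCAA) leucine, isoleucine and valine. They received vehicle or 5+3, a course of cytarabine, a nucleoside analogue that blocks DNA synthesis, with doxorubicin, a topoisomerase poison. Viable GFP-positive cells were sorted from the bone marrow of 21 mice at the time of maximum response. Each sorted sample gave an mRNA library, made with the full-length cDNA method Smart-seq2, and a library of ribosome footprints, the stretches of mRNA that ribosomes shield from nuclease. The groups held 5 mice on the amino acid diet with vehicle, 4 on the amino acid diet with 5+3, 5 on the BCAA-free diet with vehicle and 7 on the BCAA-free diet with 5+3. Levels are depth-scaled counts (CPM) as mean ± SD over these mice, and log2 changes carry the standard error (SE) of the fit. Genes are placed on the mouse genome build GRCm38.

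The mRNA libraries held 30996200 to 70437713 gene counts (median 48804734) and the footprint libraries 2697092 to 8863472 (median 4683466). Footprints varied less between mice at their lower depth. Over the 9611 protein-coding genes tested in both, the median SE of a log2 change between the diets under 5+3 was 0.153 in footprints and 0.283 in mRNA. Pseudogene rows took 21.7% to 29.5% of the footprint counts and 0.263% to 0.556% of the mRNA counts. Eno1 and its copies Eno1b and Gm4735 had mean footprint counts of 3653, 3306 and 3353 but mean mRNA counts of 46343, 335 and 51.3. Footprint changes of genes with near-identical copies are therefore uncertain as to the copy. Among the genes named here these include Eno1 and the haemoglobin, Gbp, Tgtp, Stfa, Chil3 and Chil4, Lyz1 and Lyz2, Pir, Ifi209 and histone genes. Copies of the other named genes, ribosomal protein genes and Eef1b2 among them, were not examined one by one.

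Markers of other cells and libraries that stood apart were looked at before the comparisons. Haemoglobin genes, which belong to red cells, took 0.00189% ± 0.000901 (SD, n = 5) of mRNA counts on the amino acid diet with vehicle, 0.00596% ± 0.00415 (n = 4) with 5+3, 0.00908% ± 0.00244 (n = 5) on the BCAA-free diet with vehicle and 0.000263% ± 0.000253 (n = 7) with 5+3. Ribosomal protein genes took 5.60% ± 1.65, 5.99% ± 2.10, 9.08% ± 2.18 and 5.41% ± 1.88 of mRNA counts in the same order. Their share of footprint counts was 2.34% ± 0.321, 2.20% ± 0.149, 2.34% ± 0.318 and 2.72% ± 0.286. On the first principal component of mRNA, 4 libraries stood apart from the rest. They were replicates 1 (-117), 2 (-70.7) and 5 (-256) of the BCAA-free vehicle group and replicate 7 (-53.3) of the BCAA-free 5+3 group. Footprint libraries of the 7 mice on the BCAA-free diet with 5+3 lay together at the positive end of the first footprint component.

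**Figure D1:**
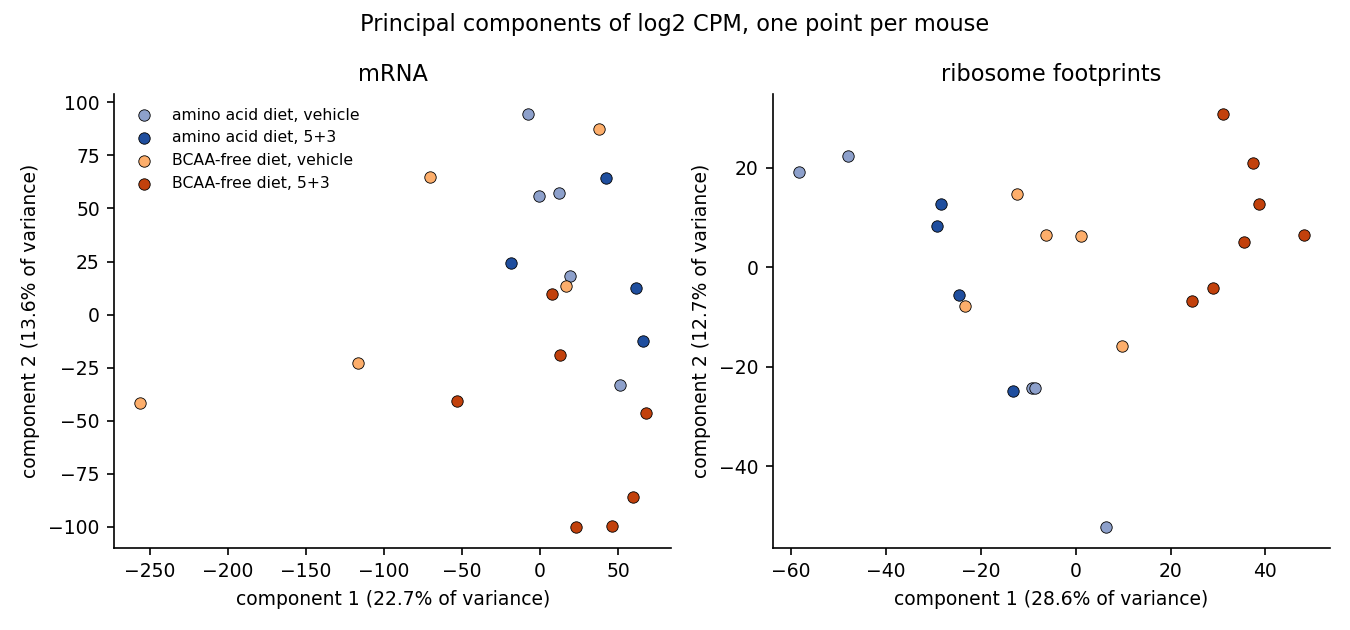
Each point is 1 mouse, placed by the first and second principal components of log2 CPM in mRNA (left, 22.7% of the variance on component 1) and in ribosome footprints (right, 28.6%), coloured by diet and treatment. In mRNA, 4 libraries of the BCAA-free diet lie below -50 on component 1, while in footprints the 7 mice on the BCAA-free diet with 5+3 lie to the right of the other groups.

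**Figure D2:**
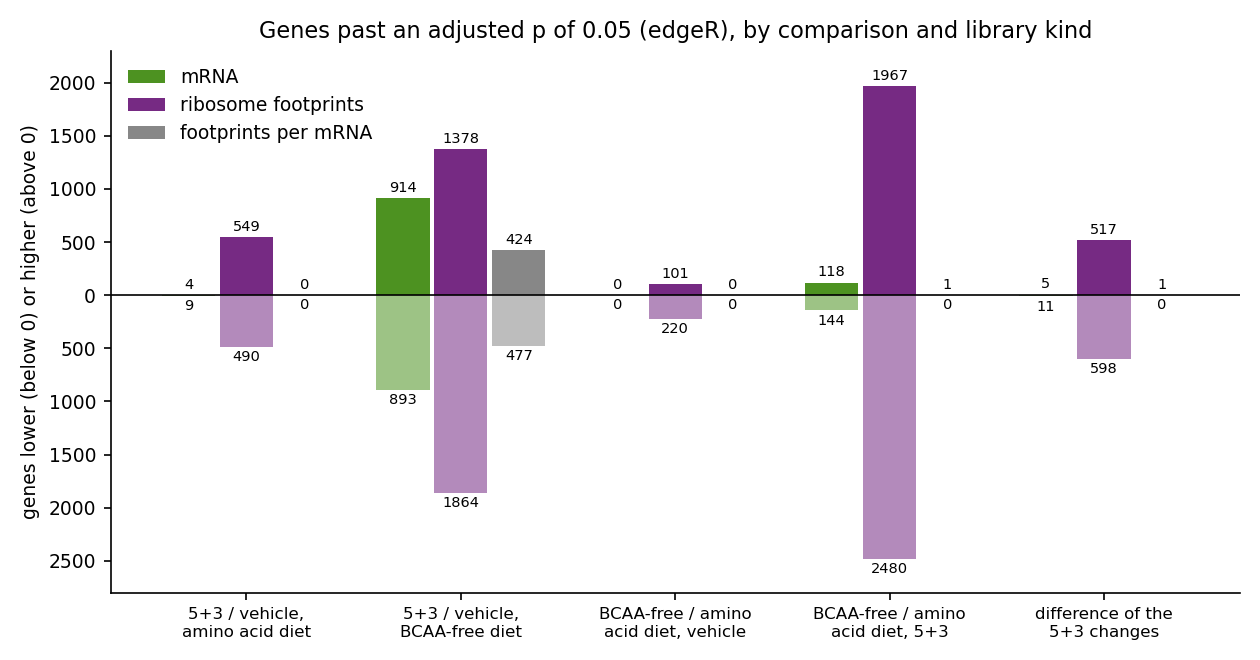
Bars give the number of genes higher (above 0) or lower (below 0) at an adjusted p of 0.05 in edgeR, in mRNA, in footprints and in footprints per mRNA, for each of the 5 comparisons. The most calls, 4447, were in footprints between the diets under 5+3, and mRNA of vehicle mice gave 0 between the diets.

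Chemotherapy on the amino acid diet raised Cdkn1a, Pim1 and Ms4a3 and lowered Irf8. Footprints of Cdkn1a (p21, an inhibitor of the cell cycle and a classical p53 target; ENSMUSG00000023067, chromosome 17, 29090979 to 29100722) rose from 3.87 ± 1.47 CPM (SD, n = 5) to 12.2 ± 4.14 CPM (n = 4), a log2 change of 1.59 ± 0.27 (SE, adjusted p = 0.000954). Its mRNA rose 2.97-fold (adjusted p = 0.0425). Pim1, a serine/threonine kinase that promotes survival (ENSMUSG00000024014, chromosome 17, 29490785 to 29496111), rose 5.46-fold in footprints (adjusted p = 0.0136) and 5.42-fold in mRNA (adjusted p = 0.0335). Ms4a3, expressed in granulocyte-monocyte progenitors (chromosome 19, 11629499 to 11640851), rose 4.21-fold in footprints (adjusted p = 0.0053) and 4.09-fold in mRNA (adjusted p = 0.0196). Irf8, the transcription factor of monocyte and dendritic cell fate (chromosome 8, 120736358 to 120756694), fell in mRNA from 71.2 ± 24.4 to 17.1 ± 7.08 CPM (log2 change -2.06 ± 0.39, adjusted p = 0.0445). For each of these 4 genes every pair of a treated and a vehicle mouse (100% of pairs) went the same way.

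In mRNA, 13 of 21114 genes passed, 4 higher and 9 lower. Largest changes, here and in the later comparisons, are ranked among genes that met the rule for named genes, with at least 10 CPM. Genes outside it, such as Cdkn1a in footprints here, can have larger changes. Beside those above, the largest falls were in Ly86 (log2 change -3.63 ± 0.63), Lat2 (-2.95 ± 0.44), Padi2 (-2.06 ± 0.35), the lysosomal protease Ctsh (-1.77 ± 0.28) and the actin regulator Evl (-1.76 ± 0.31). In footprints, 1039 of 15723 genes passed, 549 higher and 490 lower. The largest rises beyond Pim1 and Ms4a3 were in the heat shock protein Hsph1 (log2 change 1.42 ± 0.31), the vesicle coat protein Sec24d (1.21 ± 0.29), the lipopolysaccharide receptor Tlr4 (1.15 ± 0.24) and Nap1l5 (4.80 ± 1.10), whose mean of 38.7 ± 56.9 CPM rested on 1 library at 123.7 CPM. The largest falls were in the scaffold protein Ahnak (-2.97 ± 0.56), Ifi209 (-2.67 ± 0.41), fibronectin Fn1 (6.04-fold lower), the protease Ctss (-2.49 ± 0.43), Lsp1 (-2.32 ± 0.41) and lysozyme Lyz1 (-2.04 ± 0.38). Of the panel fixed for every comparison, 1 of 15 genes passed in mRNA (Cdkn1a). The others lay between -0.85 (Bckdha) and 0.60 (Slc7a5). In footprints Cdkn1a rose and Bckdha, a subunit of the BCAA dehydrogenase, fell by 0.70 (SE 0.172, adjusted p = 0.0145). The other 10 measured lay between -0.27 (Myc) and 0.34 (Slc7a5).

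Among the gene lists, 8 of 17 monocyte and macrophage genes fell in footprints and 0 rose (10 fell when adjusted over the list alone; median -0.93). The leading members were Ctss (-2.49), Lyz2 (-1.97) and Mpeg1 (-1.96). The list had an adjusted p = 0.0518 with an estimated correlation in footprints and 0.00326 in mRNA, where 1 of 21 members fell (Irf8; 7 adjusted over the list alone). The enzymes of cholesterol synthesis rose in footprints, 12 of 24 higher (16 adjusted over the list alone; median 0.57). They included Lss (1.03), Idi1 (0.77) and Fdps (0.80), with adjusted p = 0.0518 with an estimated correlation. The unfolded protein response of the endoplasmic reticulum had 13 of 24 higher (14 adjusted over the list alone), led by the chaperone Hspa5 (0.86), Sdf2l1 (0.86) and Creld2 (0.88), with adjusted p = 0.0518 with an estimated correlation. Of cytosolic heat shock genes 7 of 15 rose (11 adjusted over the list alone), such as Hsp90aa1 (0.70) and Stip1 (0.42). Glycolytic genes had 8 of 19 higher (11), such as Eno1 (0.94), Ldha (0.66) and Tpi1 (0.53), and both lists had adjusted p = 0.0603 with an estimated correlation. Of G2 and mitosis genes 15 of 40 rose (26 adjusted over the list alone), led by Bub1 (0.65), Ccna2 (0.61) and Aurkb (0.57), with adjusted p = 0.0911 with an estimated correlation. Of the p53 targets 2 of 26 rose in mRNA, Cdkn1a and Phlda3 (log2 change 3.36 ± 0.57, adjusted p = 0.0196), which made 3 adjusted over the list alone. The list had adjusted p = 0.121 with an estimated correlation. Members of these lists not counted here did not pass the test. Marker lists of other cell types had 0 members past the test over all genes in mRNA. Erythroid markers had a median of 1.68 (3 of 12 higher adjusted over the list alone; adjusted p = 0.0299 with an estimated correlation). The medians were 1.78 for T and NK cells, 1.52 for stroma and bone, 0.89 for resident macrophages, 0.77 for endothelium, 0.47 for megakaryocytes, 0.12 for mature neutrophils, -0.45 for dendritic cells, -0.46 for B cells and -0.87 for eosinophils, basophils and mast cells. With an estimated correlation their adjusted p was 0.121, 0.121, 0.0692, 0.216, 0.827, 0.943, 0.698, 0.239 and 0.537 in this order. The mRNA libraries of this 5+3 group had 24208 to 34675 genes with a count (median 33683), against 23619 to 27376 with vehicle (median 25320). Whether this bears on the marker medians was not tested.

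Leaving out 1 mouse ended mRNA calls of this comparison, at log2 changes of similar size. Of 9 such fits Irf8 lost its call in 9 (log2 changes -2.37 to -1.85), Cdkn1a in 8 (1.40 to 1.90), Pim1 in 8 (2.28 to 2.69) and Ms4a3 and Ly86 in 7 (1.94 to 2.19 and -3.88 to -3.42). Evl lost it in 7, Padi2 in 6, Lat2 and Ctsh in 3, and in footprints Bckdha and Sec24d in 2 and Pim1 and Nap1l5 in 1. In mRNA Ly86 also lost its call with no filter on low counts (adjusted p = 0.109), Cdkn1a with only the compared groups (0.0872) and Irf8 with median-ratio scaling (0.0521). In footprints Bckdha lost it without the 2 shallowest libraries (0.0634) and Nap1l5 with only the compared groups (0.0906) and in limma (0.144). In edgeR 0 genes passed without replicates 1, 2 or 3 of the amino acid 5+3 group, 3 without its replicate 4, and 5, 5, 2 and 6 without replicates 1, 2, 3 or 4 of the vehicle group, while DESeq2 called 94 and limma 802. The footprint count dropped to 564, 535 and 575 without replicates 1, 2 and 3 of the 5+3 group.

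Chemotherapy on the BCAA-free diet raised Asns, Slc7a5, Cdkn1a and Pim1 and lowered Retnlg and the haemoglobin genes. Asns, the enzyme that makes asparagine and a target of the stress factor ATF4 (ENSMUSG00000029752, chromosome 6, 7675165 to 7693209), rose in footprints from 64.2 ± 8.21 CPM (SD, n = 5) to 120.5 ± 37.7 CPM (n = 7), 1.88-fold (adjusted p = 0.000545). It rose 3.00-fold in mRNA (adjusted p = 0.00908). Slc7a5, the transporter that carries leucine and other large neutral amino acids (ENSMUSG00000040010, chromosome 8, 121881146 to 121907686), rose from 35.6 ± 4.63 to 63.3 ± 11.3 footprint CPM (log2 change 0.83 ± 0.14, adjusted p = 0.000236) and 3.37-fold in mRNA (adjusted p = 0.0105). Cdkn1a rose 2.73-fold in footprints and 2.19-fold in mRNA, and Pim1 rose 6.99-fold in footprints. Retnlg, a secreted protein of neutrophils (ENSMUSG00000022651, chromosome 16, 48872608 to 48874498), fell in footprints from 26.3 ± 6.10 to 1.87 ± 2.07 CPM (log2 change -3.68 ± 0.40, adjusted p = 2.52e-05) and 22.7-fold in mRNA. In footprints each of these 5 genes went the same way in 100% of the pairs of mice.

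In footprints 3242 of 15723 genes passed, 1378 higher and 1864 lower. Cdkn1a and the red cell gene Slc4a1 did not meet the limits of the footprint ranking and are left out of it. In mRNA 1807 of 21114 passed, 914 higher and 893 lower. The largest footprint rises after Pim1 were in Ms4a3 (1.85 ± 0.36), the clone-named gene AC131105.1 (1.45 ± 0.26), the phosphate carrier Slc20a1 (1.07 ± 0.17), the proline synthesis enzyme Aldh18a1 (1.05 ± 0.14) and the maltase Mgam (0.99 ± 0.25). The largest falls after Retnlg were in the haemoglobin genes Hbb-bt (-3.27 ± 0.35), Hbb-bs (-3.16 ± 0.34), Hba-a1 (-3.16 ± 0.37) and Hba-a2 (-3.11 ± 0.38) and in the interferon-induced GTPase Tgtp1 (-3.07 ± 0.78). The mRNA rises were led by the p53 target Phlda3 (2.75 ± 0.51), the triglyceride enzyme Dgat2 (2.60 ± 0.60), the kinase Dyrk3 (2.22 ± 0.48), Lrrc59 (2.22 ± 0.51), Zbed3 (2.17 ± 0.43) and the splicing factor Sf3b4 (2.12 ± 0.51). The mRNA falls were led by Hba-a1 (-5.49 ± 0.63), Hbb-bs (-4.81 ± 0.60), Retnlg (-4.50 ± 0.51), S100a6 (-2.81 ± 0.48), Camp (-2.54 ± 0.50) and Isg15 (-2.48 ± 0.39). In the panel, mRNA of Cdkn1a, Asns and Slc7a5 rose, while Ddit3 (-1.25 ± 0.20), the proliferation marker Mki67 (-0.75 ± 0.21) and Atf4 itself (-0.62 ± 0.20) fell. The other 9 lay between -1.11 (Bcat1) and 1.43 (Sesn2). In footprints the same 3 genes rose, and the other 9 measured lay between -0.37 (Sesn2) and 0.33 (Mdm2). Of 12 fits without 1 mouse Atf4 lost its mRNA call in 9, Mki67 in 6 and Sf3b4 in 1. With no filter on low counts Atf4 (adjusted p = 0.0766) and Sf3b4 (0.0575) lost it, and with only the compared groups Atf4 (0.0685) and Mki67 (0.0769). Without the 4 libraries apart the mRNA calls of Hba-a1, Hbb-bs and Retnlg passed, while Phlda3, Dgat2, Dyrk3, Lrrc59, Zbed3, Sf3b4, S100a6, Camp, Isg15, Cdkn1a, Asns, Slc7a5, Ddit3, Mki67 and Atf4 lost theirs, with adjusted p from 0.0904 (S100a6) to 0.393 (Mki67).

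Of the targets of ATF4, 14 of 25 rose and 1 fell in footprints (the same numbers adjusted over the list alone; median 0.53). Aldh18a1 (1.05), Psat1 (0.85) and Shmt2 (0.70) of proline, serine and glycine synthesis led it, with adjusted p = 0.233 with an estimated correlation. Cytosolic aminoacyl-tRNA synthetases had 11 of 20 higher (14 adjusted over the list alone), such as Eprs (0.77), Lars (0.71) and Aars (0.57). Translation factors had 21 of 45 higher and 1 lower (26 and 2), such as Eif2b3 (0.55) and Eif2s3x (0.39), and both lists had adjusted p = 0.233 with an estimated correlation. Of MHC class I presentation genes 12 of 14 fell (14 adjusted over the list alone), led by B2m (-1.33), H2-D1 (-1.33) and Tapbp (-0.83), with adjusted p = 0.201 with an estimated correlation. Interferon-stimulated genes had 17 of 40 lower (24), led by Stat2, Parp14 (-1.70) and Trim30a (-0.73), with adjusted p = 0.311 with an estimated correlation. All 9 markers of mature neutrophils fell in footprints (9 adjusted over the list alone), such as Retnlg, Mmp8 (-3.02) and Mmp9 (-2.35), with adjusted p = 0.176 with an estimated correlation. In mRNA 8 of 9 fell (9), with adjusted p = 0.0103 with an estimated correlation. Of 7 erythroid markers 5 fell (5 adjusted over the list alone; median -3.16), which passed with an estimated correlation (adjusted p = 0.0212). The haemoglobin genes led it, with Slc4a1 (-3.31), the anion exchanger of red cells. Of monocyte and macrophage genes 9 of 17 fell (9 adjusted over the list alone), with adjusted p = 0.201 with an estimated correlation. Of the 13 proteins encoded in mitochondrial DNA 11 fell (12 adjusted over the list alone), such as mt-Co3 (-0.72) and mt-Atp6 (-0.62), with adjusted p = 0.233 with an estimated correlation. Mitochondrial ribosomal RNA, too, took 8.36% ± 1.04 (SD) of footprint counts with vehicle and 6.32% ± 1.16 with 5+3 on this diet. Whether these falls share a cause was not tested. Of 22 p53 targets 6 rose and 1 fell in footprints (8 and 4 adjusted over the list alone). Cdkn1a and Pmaip1 (0.97) were among the rises and Apaf1 (-0.63) was the fall, and the list did not pass (adjusted p = 0.109). Of ribosomal protein genes 22 of 82 rose in footprints (25 adjusted over the list alone; median 0.20), such as Rps18 (0.39) and Rpl14 (0.33). In mRNA 14 fell (50; median -0.76), such as Rpl13a (-1.17) and Rps27a (-1.13), and the lists had adjusted p = 0.43 and 0.394 with an estimated correlation. Without the 4 mRNA libraries that stood apart the mRNA median was -0.44 and 0 of 82 passed.

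The share of rises depended on the scaling: among protein-coding genes 565 rose and 1535 fell in footprints, and when only protein-coding rows entered the fit 1042 rose and 1144 fell. Without replicate 5 of the BCAA-free vehicle group the footprint count was 2084. The mRNA count was 19 without the 4 libraries apart, 546, 1202 and 974 without replicates 2, 3 and 5 of the vehicle group, and 739, 728, 1056 and 546 without replicates 1, 2, 4 and 5 of the 5+3 group.

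In vehicle mice on the BCAA-free diet footprints of Retnlg, Ccl9 and Fbp1 were higher and those of Olfm4 lower. Retnlg rose 3.09-fold to 26.3 ± 6.10 CPM (SD, n = 5 in both groups), a log2 change of 1.63 ± 0.39 (adjusted p = 0.0356). The chemokine Ccl9 (ENSMUSG00000019122, chromosome 11, 83572917 to 83578636) rose 2.40-fold (adjusted p = 0.0403), and Fbp1, a rate-limiting enzyme of gluconeogenesis (ENSMUSG00000069805, chromosome 13, 62864753 to 62888298), rose 2.15-fold (adjusted p = 0.0127). Olfm4, a neutrophil granule protein, fell from 164.8 ± 27.8 to 62.1 ± 15.3 CPM (log2 change -1.41 ± 0.34, adjusted p = 0.0387). For these 4 genes 100% of the pairs of mice went the same way. Of 10 fits without 1 mouse, the call was lost in 9 for Olfm4 (log2 changes -1.52 to -1.30), in 7 for Retnlg (1.48 to 1.83), in 7 for Ccl9 (1.13 to 1.38) and in 0 for Fbp1. With no filter on low counts Olfm4 (adjusted p = 0.0511), Retnlg (0.0586) and Ccl9 (0.0663) did not pass, nor did they without the 2 shallowest libraries (0.055, 0.0701 and 0.0693).

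In footprints 321 of 15723 genes passed, 101 higher and 220 lower. The other large rises were in Ptov1 (0.81 ± 0.22; lost in 8 of 10 fits without 1 mouse), the acyl-CoA thioesterase Acot1 (0.81 ± 0.18) and the endolysosomal channel Tpcn1 (0.79 ± 0.16). The other large falls were in Stfa3 (-2.37 ± 0.52), Ifi209 (-1.44 ± 0.34), Lilra6 (-1.41 ± 0.29), Pirb (-1.40 ± 0.28) and Pira2 (-1.39 ± 0.32), genes of families with similar copies, whose sharing of reads was not tested. Of 10 fits without 1 mouse Ifi209 lost its call in 6, Pira2 in 4 and Stfa3 in 3, and Pira2 lost it with only the compared groups (adjusted p = 0.0919). In mRNA 0 of 21114 genes passed in edgeR, against 2363 with an unadjusted p under 0.05, 161 in DESeq2, 107 of them higher, and 1 in limma. Without replicate 2 of the BCAA-free vehicle group 1 gene passed. Of the panel 0 genes passed in edgeR. The 15 in mRNA lay between -1.19 (Chac1) and 1.03 (Bcat1), and the 12 in footprints lay between -0.33 (Asns) and 0.49 (Sesn2).

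Of the interferon-stimulated genes 6 of 40 fell in footprints and 0 rose (22 fell adjusted over the list alone; median -0.67), led by Ifit3 (-3.27), Ifit1 (-2.27), Slfn5 (-1.96) and Oas1a (-0.91), with adjusted p = 0.581 with an estimated correlation. In mRNA 0 of 45 passed, 16 fell adjusted over the list alone, and the adjusted p was 0.17 with an estimated correlation. Of the erythroid markers 1 of 7 rose (3 adjusted over the list alone; median 1.17), Slc4a1 (1.76), with adjusted p = 0.581 with an estimated correlation. Aminoacyl-tRNA synthetases had 2 of 20 lower (7 adjusted over the list alone), Mars (-0.53) and Aars (-0.49), with adjusted p = 0.635 with an estimated correlation. Of monocyte and macrophage genes 1 of 17 fell, Adgre1 (-1.29; 2 adjusted over the list alone), with adjusted p = 0.581 with an estimated correlation. Replication-dependent histones had 0 of 59 past the test over all genes but 58 higher adjusted over the list alone (median 0.54), with adjusted p = 0.581 with an estimated correlation. Ribosomal protein mRNA had a median of 0.77 with 0 of 82 members past the test over all genes or adjusted over the list alone (adjusted p = 0.469 with an estimated correlation), beside the 3 BCAA-free vehicle libraries that stood apart. The footprint count was 163 without replicate 5 of the amino acid vehicle group, 164, 206 and 211 without replicates 1, 2 and 3 of the BCAA-free vehicle group, and 599 without the 2 shallowest libraries, replicates 1 and 2 of the amino acid vehicle group.

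Between the diets under 5+3, mice on the BCAA-free diet had lower Isg15, Fdps and Hspa5 and higher Cirbp. Isg15, a ubiquitin-like protein induced by interferon, stood at 31.8 ± 12.9 mRNA CPM on the amino acid diet (SD, n = 4) and 4.32 ± 2.50 CPM on the BCAA-free diet (n = 7), 7.37-fold lower (adjusted p = 0.000533). In footprints it stood at 10.9 and 1.43 CPM, 7.03-fold lower (adjusted p = 2.23e-05). Fdps, the farnesyl diphosphate synthase of the cholesterol pathway, was 2.92-fold lower in footprints (log2 change -1.55 ± 0.11, adjusted p = 1.18e-09) and 2.63-fold lower in mRNA (adjusted p = 0.000274). The chaperone Hspa5 (BiP) was 1.95-fold lower in footprints (log2 change -0.97 ± 0.13, adjusted p = 6.96e-06). Cirbp, an RNA-binding protein induced by cold and stress (ENSMUSG00000045193, chromosome 10, 80165990 to 80172786), was higher by a log2 change of 2.76 ± 0.32 in footprints (8.35 ± 1.35 against 57.5 ± 18.8 CPM, adjusted p = 1.03e-05). The mRNA change was 3.21 ± 0.37 (44.1 ± 8.22 against 407 ± 162 CPM, adjusted p = 0.0001), in 100% of the pairs of mice.

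In footprints 4447 of 15723 genes passed, 1967 higher and 2480 lower. In mRNA 262 of 21114 passed, 118 higher and 144 lower. The largest footprint rises after Cirbp were in Fbp1 (2.05 ± 0.25), Ccl9 (2.00 ± 0.32), the chitinase-like genes Chil3 (1.80 ± 0.38) and Chil4 (1.76 ± 0.39), and the haem-binding membrane protein Pgrmc1 (1.63 ± 0.20; ENSMUSG00000006373, chromosome X, 36598193 to 36606079). The largest falls were in guanylate-binding and other interferon-induced GTPases, Gbp5 (-4.04 ± 0.67; chromosome 3, 142496934 to 142522344), Tgtp1 (-3.94 ± 0.79), Tgtp2 (-3.91 ± 0.77), Gbp6 (-3.87 ± 0.67) and Gbp2 (-3.76 ± 0.68), and in Nap1l5 (-3.91 ± 0.85), which rested on the same library at 123.7 CPM. In mRNA, the rises after Cirbp were in Zbed3 (3.06 ± 0.50), the mast cell and basophil protease Prss34 (2.99 ± 0.63), Impdh1, an enzyme of guanine nucleotide synthesis (2.80 ± 0.48), Calml4 (2.75 ± 0.54) and the receptor kinase Flt3 (2.69 ± 0.53). The mRNA falls were in the chemokine Cxcl10 (-4.19 ± 0.70), the acute-phase gene Saa3 (-3.51 ± 0.41), the stefins Stfa3 (-3.17 ± 0.48), BC100530 (-3.05 ± 0.51) and Stfa2 (-3.00 ± 0.47), and Gbp2 (-2.97 ± 0.74). Gbp2 lost its mRNA call in 10 of 11 fits without 1 mouse, with no filter on low counts (adjusted p = 0.129) and without the 4 libraries apart (0.0897). In the panel Slc7a5 (0.73 ± 0.15) and Bckdha (0.55 ± 0.16) were higher and Mki67 (-0.56 ± 0.15) and Bcat2 (-0.29 ± 0.10) lower in footprints. Bcat2 lost its call in 5 of 11 fits without 1 mouse, with no filter on low counts (adjusted p = 0.157) and with protein-coding rows only (log2 change -0.20, adjusted p = 0.113). The other 8 of the panel lay between -0.42 (Atf4) and 0.26 (Asns). In mRNA Ddit3 was lower (-0.96 ± 0.22; lost in 5 of 11 fits without 1 mouse and, with adjusted p = 0.0891, with no filter on low counts) and the other 14 lay between -1.45 (Chac1) and 1.16 (Slc7a5). The smallest adjusted p among these 14 in edgeR was 0.0543 (Atf4), close to the threshold. Of the same 11 fits calls were lost in mRNA in 3 for Prss34 and in 2 for Calml4 and Flt3, and in footprints in 1 for Bckdha, Mki67 and Nap1l5.

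Of the interferon-stimulated genes 38 of 40 fell in footprints (39 adjusted over the list alone; median -1.47), led by Oas3 (-2.61), Samd9l (-1.60), Ifit1 (-2.86) and Trim30a (-1.06), with adjusted p = 0.162 with an estimated correlation. In mRNA 12 of 45 fell (28 adjusted over the list alone; median -1.41). Isg15 (-2.88), Parp14 (-2.68) and Cxcl10 were among the members with the smallest adjusted p of the list, which passed with an estimated correlation (adjusted p = 0.0155). Cholesterol synthesis had 18 of 24 lower in footprints (21 adjusted over the list alone; median -0.82), with Mvd (-2.28), Sqle (-1.62) and Stard4 (-1.46) after Fdps. It had 3 of 24 lower in mRNA (5), and both passed with an estimated correlation (adjusted p = 0.0352 and 0.0214). The unfolded protein response had 20 of 24 lower (20 adjusted over the list alone), including Creld2 (-1.30), Hyou1 (-0.82) and Pdia4 (-0.79), with adjusted p = 0.0529 with an estimated correlation. Glycolysis had 14 of 19 lower (14 adjusted over the list alone), such as Pfkl (-1.42), Pfkp (-0.83) and Hk3 (-0.74). Cytosolic heat shock had 9 of 15 lower (10), such as Hsph1 (-2.58) and Dnaja1 (-0.82), and both lists had adjusted p = 0.19 with an estimated correlation. Of MHC class I genes 12 of 14 fell (13 adjusted over the list alone), such as H2-K1 (-1.57) and Psmb9 (-1.33), with adjusted p = 0.317 with an estimated correlation. Of ribosomal proteins 38 of 82 rose (48 adjusted over the list alone), such as Rpl38 (0.55), Rpl36 (0.53) and Rpl24 (0.44), with adjusted p = 0.672 with an estimated correlation. Of BCAA catabolism genes 4 of 24 rose and 6 fell (5 and 6 adjusted over the list alone). Dbt (0.65) and Echs1 (0.68) rose and Mcee (-0.73) fell, and the list did not pass (adjusted p = 0.629). Of ATF4 targets 6 of 25 rose and 3 fell (8 and 3 adjusted over the list alone). Pycr1 (1.22) and Phgdh (1.12) rose and Cebpb (-0.75) fell, and the list did not pass either (adjusted p = 0.229). Red cell and neutrophil markers moved in the same comparison. In footprints 6 of 7 erythroid markers fell (6 adjusted over the list alone; adjusted p = 0.0686 with an estimated correlation). Of 9 mature neutrophil markers 4 fell in footprints (4; adjusted p = 0.684 with an estimated correlation) and 3 in mRNA (8; adjusted p = 0.0214 with an estimated correlation).

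No single left-out mouse moved the footprint count by over 1.5 times. With protein-coding rows only 1384 genes rose and 1635 fell, against 860 and 2068 of these genes in the fit over all rows. The mRNA count was 132, 101, 112 and 101 without replicates 1, 2, 3 and 4 of the amino acid 5+3 group, 776 in DESeq2 and 509 without the 4 libraries apart.

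**Figure D3:**
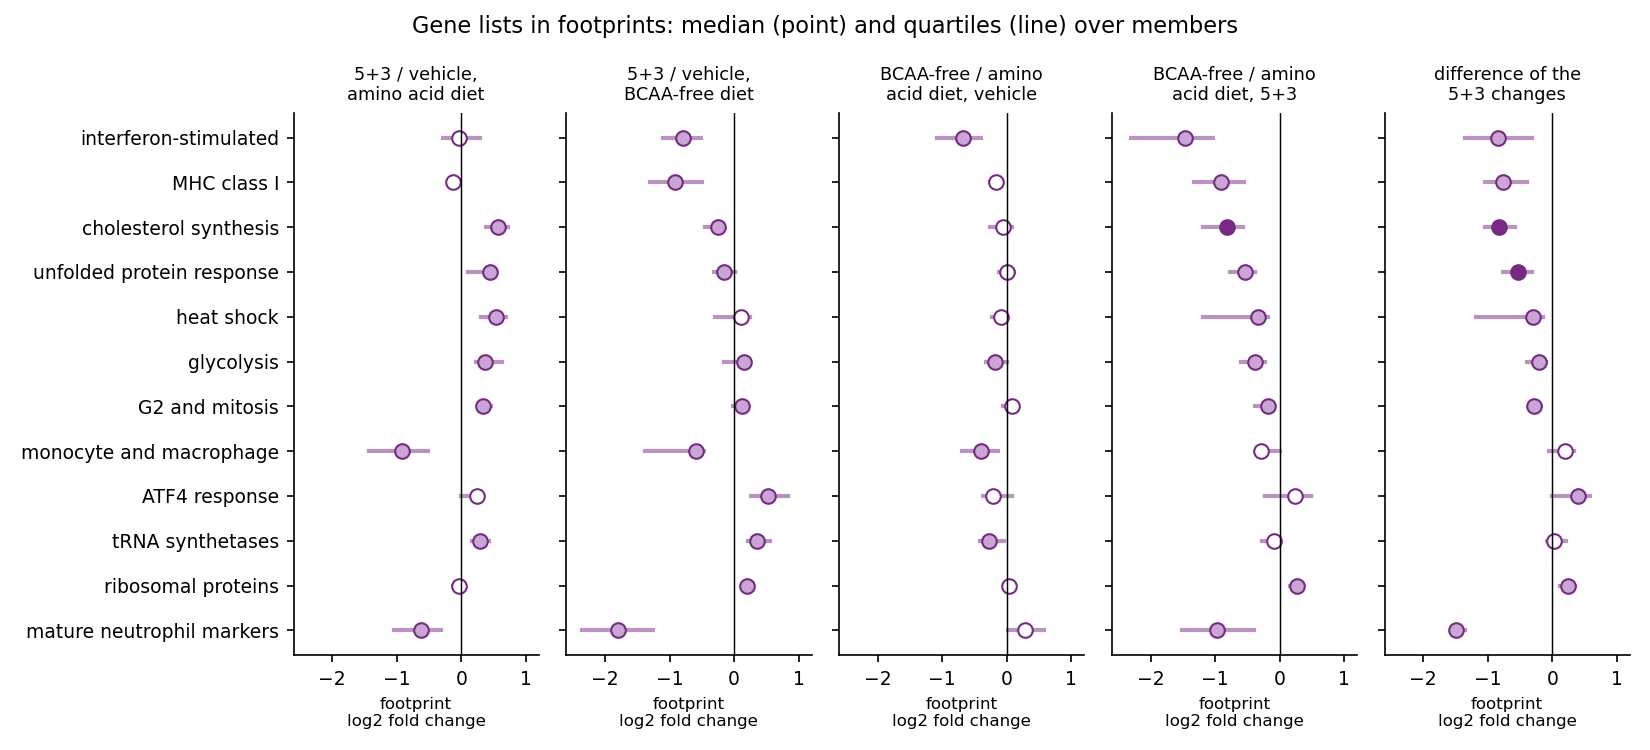
Points are the median footprint log2 change over the measured members of 12 gene lists and lines run between the quartiles of the members, 1 panel per comparison. Dark points passed camera with an estimated correlation (adjusted p under 0.05), pale points passed only with the preset correlation of 0.01, and open points did not pass. The interferon-stimulated list has medians of -0.67 in vehicle mice and -1.47 under 5+3 between the diets, and cholesterol synthesis has 0.57 on the amino acid diet and -0.25 on the BCAA-free diet after 5+3.

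The interaction tests whether chemotherapy changed a gene differently on the BCAA-free diet than on the amino acid diet. Cirbp footprints fell with 5+3 on the amino acid diet, from 22.4 ± 5.29 to 8.35 ± 1.35 CPM (SD, n = 5 and 4; log2 change -1.40 ± 0.34, adjusted p = 0.0193). They stood at 34.7 ± 10.6 and 57.5 ± 18.8 CPM (n = 5 and 7) on the BCAA-free diet, a difference of log2 changes of 2.11 ± 0.43 (adjusted p = 0.00781). The splicing factor Srsf5 (ENSMUSG00000021134, chromosome 12, 80945495 to 80950507) fell from 137 ± 13.2 to 70.4 ± 6.27 CPM on the amino acid diet and rose from 120.1 ± 26.4 to 217 ± 33.1 CPM on the BCAA-free diet (difference 1.81 ± 0.18, adjusted p = 2.87e-06). Haemoglobin genes showed the opposite. Hbb-bs footprints stood at 19.8 ± 11.3 and 29.7 ± 6.47 CPM on the amino acid diet and at 41.8 ± 11.0 and 4.48 ± 2.07 CPM on the BCAA-free diet (difference -3.84 ± 0.50, adjusted p = 0.000543).

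In footprints 1115 of 15723 genes passed, 517 with a higher and 598 with a lower change on the BCAA-free diet. Of these 360 were pseudogene rows, and among protein-coding genes 116 were higher and 476 lower. In mRNA 16 of 21114 passed, 5 higher and 11 lower. Other positive footprint differences were in the phosphatase Ptpn13 (1.87 ± 0.30), the linker histone H1f0 (1.40 ± 0.30), Evl (1.29 ± 0.38) and Pgrmc1 (1.19 ± 0.28). Other negative ones were in Hbb-bt (-4.02 ± 0.52), Hba-a1 (-3.50 ± 0.54), Hba-a2 (-3.41 ± 0.55), Gbp5 (-3.35 ± 0.93) and Gbp6 (-3.33 ± 0.90). In mRNA Fbp1 (2.05 ± 0.39), the chromatin protein Hmgb3 (1.48 ± 0.25), the peroxisomal import receptor Pex7 (1.36 ± 0.26), D16Ertd472e (1.34 ± 0.25) and Adss of AMP synthesis (1.09 ± 0.21) were positive. Negative in mRNA were Hba-a1 (-6.86 ± 0.89), Hbb-bs (-6.65 ± 0.88), Saa3 (-4.06 ± 0.59), the calprotectin subunits S100a9 (-3.46 ± 0.59) and S100a8 (-3.41 ± 0.59) and Wfdc21 (-3.33 ± 0.57). Of 21 fits without 1 mouse, calls were lost in mRNA in 17 for Pex7, 15 for Fbp1, 12 for Adss, 10 for D16Ertd472e, 3 for Hmgb3, 2 for S100a8 and S100a9 and 1 for Wfdc21, and in footprints in 15 for Gbp5, 14 for Evl and 9 for Gbp6. With no filter on low counts Hmgb3 (adjusted p = 0.0589), S100a9 (0.0653), S100a8 (0.0708), Pex7 (0.0793), D16Ertd472e (0.0849) and Adss (0.101) lost their mRNA call and Gbp6 (0.0591) and Gbp5 (0.0648) their footprint call. Pex7 also lost it with median-ratio scaling (0.06) and Gbp6 in limma (0.0653). Without the 4 libraries apart the mRNA calls of Hba-a1, Hbb-bs and Saa3 passed, and those of Fbp1, Hmgb3, Pex7, D16Ertd472e, Adss, S100a9, S100a8 and Wfdc21 did not (adjusted p from 0.123 to 0.163). In the panel Bcat2, the mitochondrial BCAA transaminase, passed in footprints (-0.48 ± 0.14, adjusted p = 0.0382), with the other 11 between -0.52 (Sesn2) and 0.59 (Asns). Its call was lost in 11 of 21 fits without 1 mouse (-0.58 to -0.42), with no filter on low counts (adjusted p = 0.147) and with protein-coding rows only (adjusted p = 0.1). In mRNA 0 of 15 passed in edgeR with the main settings, and values ran from -1.48 (Ddit3) to 1.35 (Sesn2). The smallest adjusted p among them was 0.0721 (Ddit3), close to the threshold.

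Cholesterol synthesis had 15 of 24 footprint differences negative and past the test (19 adjusted over the list alone; median -0.83). They included Mvd (-2.17), Lss (-1.27), Fdps (-1.25) and Idi1 (-0.98), and the list passed with an estimated correlation (adjusted p = 0.0435). The unfolded protein response had 13 of 24 negative (18 adjusted over the list alone; median -0.54), including Creld2 (-1.23), Hspa5 (-1.19) and Syvn1 (-1.09), and passed too (adjusted p = 0.049). Erythroid markers had 5 of 7 negative in footprints (7 adjusted over the list alone) and 4 of 12 in mRNA (8), and passed in both (adjusted p = 0.00662 and 5.1e-05 with an estimated correlation). Mature neutrophil markers had 1 of 9 negative in footprints, Mmp9 (2 adjusted over the list alone; adjusted p = 0.613 with an estimated correlation). In mRNA 0 of 9 passed in edgeR over all genes, and 9 passed adjusted over the list alone (adjusted p = 0.0235 with an estimated correlation). Of interferon-stimulated genes 3 of 40 were negative, Stat2, Parp9 and Cxcl10 (11 adjusted over the list alone; median -0.84), with adjusted p = 0.655 with an estimated correlation. Heat shock had 3 of 15 negative (5 adjusted over the list alone) with adjusted p = 0.537 with an estimated correlation. Of ATF4 targets 1 of 25 was positive, Psat1, with 0 adjusted over the list alone and adjusted p = 0.67 with an estimated correlation. The footprint count was 544 and 700 without replicates 1 and 3 of the amino acid 5+3 group, 594 without replicate 5 of the BCAA-free vehicle group, 2102 without the 2 shallowest libraries and 476 with protein-coding rows only, of which 201 were positive. The mRNA count was 10, 10 and 7 without replicates 1, 2 and 4 of the amino acid vehicle group, 10, 8, 9 and 5 without replicates 1, 2, 3 and 4 of the amino acid 5+3 group, 29 and 26 without replicates 1 and 4 of the BCAA-free vehicle group, 27 without replicate 3 of the BCAA-free 5+3 group and 7 without the 4 libraries apart. With median-ratio scaling 4 were positive and 18 negative.

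**Figure D4:**
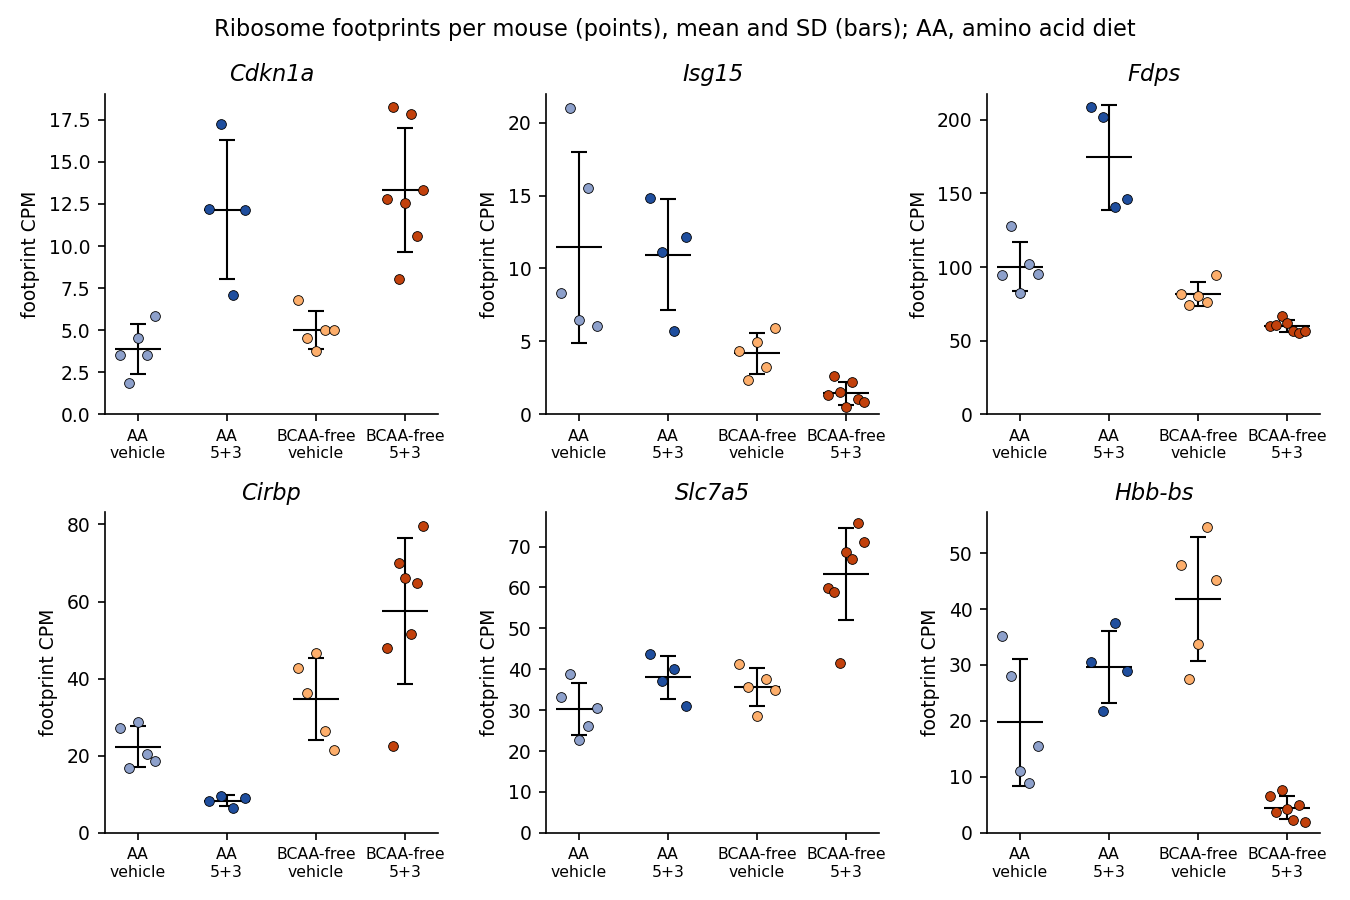
Points are the footprint CPM of 6 genes in each mouse, and bars the group mean and SD (n = 5, 4, 5 and 7 from left to right). Isg15 lies between 5.72 and 14.8 CPM in the 4 mice on the amino acid diet with 5+3 and between 0.474 and 2.64 CPM in the 7 on the BCAA-free diet with 5+3, and Cirbp between 6.54 and 9.60 CPM and between 22.4 and 79.6 CPM in the same groups.

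Footprints per mRNA, the translational efficiency, changed on the BCAA-free diet with chemotherapy for 901 of 12097 genes, 424 higher and 477 lower. Of these 158 were pseudogene rows, and among protein-coding genes 252 were higher and 422 lower. When only protein-coding rows entered the fit 351 were higher and 430 lower. Of ribosomal protein genes 44 of 82 were higher and 0 lower (76 adjusted over the list alone; median 1.16). They included Rpl13a (1.63), Rps27a (1.47), Rps3a1 (1.39) and Rpl8 (1.31), with adjusted p = 0.815 with an estimated correlation. Among single genes Hba-a1 (2.79 ± 0.68), Hbb-bs (2.03 ± 0.58), the clone-named row CT010467.1 (1.99 ± 0.60), the calcium channel Itpr2 (1.78 ± 0.38), Rps24 (1.73 ± 0.44) and the elongation factor Eef1b2 (1.70 ± 0.42) were highest. Hbb-bs mRNA was 0.237 to 3.69 CPM in the BCAA-free 5+3 mice, so its ratio rests on a low mRNA level there. Whether CT010467.1 is translated was not looked at. Lowest were the endosomal GTPase Rab5a (-2.29 ± 0.51), Pstpip2 (-2.27 ± 0.46), Cdc16 of the anaphase-promoting complex (-2.22 ± 0.51), Gosr2 (-1.89 ± 0.47), Rad18 (-1.88 ± 0.44) and Ergic1 (-1.77 ± 0.36). In the panel Mki67 was higher (0.81 ± 0.20) and the other 11 lay between -1.57 (Sesn2) and 0.78 (Atf4). Each of these single genes lost its call in 5 to 9 of 12 fits without 1 mouse. Mki67 lost it with no filter on low counts (adjusted p = 0.119) and without the mouse block (0.0568), CT010467.1 without that block (0.096), and Hbb-bs without it (0.0899) and in limma (0.0515).

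These calls depended on which mice entered. Without the 4 mice whose mRNA libraries stood apart 0 genes passed in edgeR, and the median of the ribosomal protein list was 0.94 with 0 members called. Without 1 mouse the count was 323, 4, 151, 1359 and 55 for replicates 1 to 5 of the vehicle group and 8, 10, 1635, 12, 5 and 1868 for replicates 1, 2, 3, 4, 5 and 7 of the 5+3 group. With one scaling over both kinds of library 448 were higher and 315 lower.

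In the other comparisons edgeR found few or no changes of translational efficiency. On the amino acid diet chemotherapy gave 0 genes (333 with an unadjusted p under 0.05; 1 in DESeq2 and 9 in limma), with the 12 panel genes between -0.40 (Mdm2) and 0.38 (Mki67). Between the diets in vehicle mice there were 0 (1083 unadjusted; 0 in DESeq2 and 0 in limma), with the panel between -0.44 (Atf4) and 1.08 (Sesn2), and ribosomal proteins had a median of -0.77 with 0 of 82 called (adjusted p = 0.826 with an estimated correlation). Between the diets under 5+3 there was 1, the pseudogene Gm14686 (1.61 ± 0.24, adjusted p = 0.00677), with 882 unadjusted, 18 in DESeq2 and 179 in limma, and the panel lay between -0.45 (Asns) and 0.46 (Atf4). The interaction gave 1, the pseudogene Gm4977 (3.62 ± 0.57, adjusted p = 0.0239), with 1429 unadjusted, 7 in DESeq2 and 2 in limma, and the panel lay between -1.52 (Sesn2) and 0.91 (Atf4). Both pseudogenes were named after their values were seen. The first call was lost without replicates 3 or 4 of the amino acid 5+3 group (0 genes), with 2 genes without replicate 2 of that group or replicates 2 or 5 of the BCAA-free 5+3 group. The interaction call was lost (0 genes) without any 1 of replicates 2 and 5 of the amino acid vehicle group, 1, 2 and 4 of the amino acid 5+3 group, 3, 4 and 5 of the BCAA-free vehicle group and 1, 2, 3 and 5 of the BCAA-free 5+3 group.

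Changes in mRNA and in footprints were set side by side over 9611 protein-coding genes tested in both. Across genes, which are not independent replicates, the log2 changes correlated with Pearson r = 0.671 (Spearman rho = 0.576) for the diets under 5+3, 0.512 (0.442) for chemotherapy on the amino acid diet, 0.431 (0.346) on the BCAA-free diet, 0.348 (0.27) for the interaction and 0.344 (0.3) for the diets in vehicle mice. For the diets under 5+3, 63 genes rose and 104 fell in both kinds of library, where independent lists would share 7.83 and 23, and 0 went opposite ways. For chemotherapy on the BCAA-free diet the numbers were 163 and 236, against 44.3 and 83, with 16 opposite, and on the amino acid diet 3 and 6, against 0.105 and 0.236. Both kinds of library came from the same lysates and share the deviations of each mouse, so the numbers for independent lists are not the chance values of these overlaps. Between the diets, which share no libraries, chemotherapy raised 96 and lowered 128 protein-coding genes in footprints on both, where independent lists would share 19.4 and 45.6, and 28 went opposite ways (r = 0.237). In footprints the BCAA-free diet raised 28 and lowered 91 of these genes both in vehicle and in 5+3 mice, where independent lists would share 5.68 and 28.8, and 7 went opposite ways (r = 0.427). In mRNA the changes correlated little across genes, and few genes passed on the amino acid diet. Chemotherapy raised 4 protein-coding genes on that diet, and all 4 also rose on the BCAA-free diet. It lowered 8 on the amino acid diet, of which 1 fell on both. Independent lists would share 0.23 and 0.387, and 0 went opposite ways (r = 0.0249, Spearman rho = 0.154). For the diets in vehicle and in 5+3 mice r was -0.0356, and 0 genes passed in vehicle mice.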

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

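The tests of red cell and neutrophil RNA, shared reads, temperature, short mRNAs and ribosomal protein footprints were chosen only after the result was seen, and the other tests were written down before. In 360 groups of 4 to 7 mice, 28 values lay far from the rest of their group by Dixon's ratio of the gap to the range, where chance gives about 1 in 20, or 18.

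Replicate 3 of the BCAA-free 5+3 group stood apart in neutrophil genes. In mRNA its gap ratio was 0.864 for Retnlg (27.5 CPM, the others 2.63 to 6), 0.644 for S100a6, 0.865 for Camp (522 CPM), 0.744 for S100a9 and 0.638 for S100a8. In footprints it was 0.754 for Retnlg, 0.658 for Lyz1, 0.677 for Olfm4 and 0.661 for Lilra6. In the same group replicate 2 stood apart in Gbp2 mRNA (0.619) and Mgam footprints (0.599), and replicate 7 in Calml4 mRNA (0.622).

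In the amino acid vehicle group replicate 2 stood apart in mRNA of Cxcl10 (0.713) and Saa3 (0.838) and in footprints of AC131105.1 (0.822), Mgam (0.78) and Tpcn1 (0.87), and replicate 4 in Fbp1 (0.716). In the BCAA-free vehicle group replicate 2 stood apart in Retnlg mRNA (0.796), replicate 3 in Flt3 mRNA (0.722) and in total footprint count (0.854), and replicate 5 in Nap1l5 footprints (0.841). In the amino acid 5+3 group the footprints of Nap1l5 stood apart in replicate 2 (0.897), those of Hba-a1 (0.83), Acot1 (0.867) and H1f0 (0.892) in replicate 3, and those of Chil3 (0.934) and Chil4 (0.91) in replicate 1.

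The interaction test found a different response to chemotherapy between the diets for 16 genes in mRNA, 1115 in footprints and 1 in translational efficiency. The log2 differences in mRNA were 2.05 for Fbp1, 1.48 for Hmgb3, 1.36 for Pex7, 1.34 for D16Ertd472e, 1.09 for Adss, -6.86 for Hba-a1, -6.65 for Hbb-bs, -4.06 for Saa3, -3.46 for S100a9, -3.41 for S100a8 and -3.33 for Wfdc21. In footprints they were 2.11 for Cirbp, 1.87 for Ptpn13, 1.81 for Srsf5, 1.40 for H1f0, 1.29 for Evl, 1.19 for Pgrmc1, -4.02 for Hbb-bt, -3.84 for Hbb-bs, -3.50 for Hba-a1, -3.41 for Hba-a2, -3.35 for Gbp5 and -3.33 for Gbp6.

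Other splits of the same mice into groups of these sizes tested whether chance could give as many genes. In mRNA chance was unlikely for chemotherapy on the amino acid diet (13 genes, highest other split 1; 1 of 60 splits as large), on the BCAA-free diet (1807, 490; 1 of 60) and the diets under 5+3 (262, 21; 1 of 60). The first of these counts was 0 without replicate 1 of the amino acid 5+3 group. The second was 19 without the 4 mRNA libraries that stood apart. For the interaction (16, 1626; 2 of 60) the splits moved mice between the diets within each treatment. They took away every effect of the diet, so they cannot exclude chance for an interaction alone. The split that called 1626 genes points to a structure of the mRNA libraries other than the groups. For the diets in vehicle mice 0 genes were called (highest other split 2), so that 60 of 60 splits call as many and the count says nothing about chance. In footprints chance was unlikely for chemotherapy on the amino acid diet (1039, 727; 1 of 100), on the BCAA-free diet (3242, 211; 1 of 100) and the diets under 5+3 (4447, 711; 1 of 100). For the diets in vehicle mice (321, 439; 2 of 100) the share was also under 0.05. Another split called 439 genes there, more than the real 321, so chance is not excluded for this count. The splits cannot tell a group from a batch, if the suffix B of the amino acid vehicle mice marks one. For the interaction in footprints (1115, 950; 1 of 100) chance stays open for the reason given for mRNA. In translational efficiency chance was unlikely by the share of splits for chemotherapy on the BCAA-free diet (901, 137; 1 of 31). That count ran from 4 to 1868 with 1 mouse left out and was 0 without the 4 mice whose mRNA libraries stood apart. A chance placement of a few such mice is therefore not excluded. The diets under 5+3 and the interaction gave 1 gene each against 0 in the other splits (1 of 21 each), the smallest share that 21 splits allow. Both calls were lost without single mice. For chemotherapy on the amino acid diet (0, 0; 21 of 21) and the diets in vehicle mice (0, 20; 21 of 21) a count of 0 again says nothing about chance.

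Interferon-stimulated genes were lower in BCAA-free than in amino acid mice under 5+3. No single mouse accounts for it, since at least 30 of 40 members were lower in footprints whichever mouse was left out. Leaving out more than 1 of these mice at a time was not tried in footprints, so a few mice together are not excluded. Reads shared between gene copies do not account for it, since the mRNA median was -1.41. Less RNA of red cells, which the lysis and the sort of viable GFP-positive cells should remove, cannot be excluded under 5+3. There the red cell markers had an mRNA median of -2.89. In vehicle mice the interferon footprint median was also below 0, at -0.67 (6 of 40 lower, 22 adjusted over the list alone, adjusted p = 0.581 with an estimated correlation), while red cell markers had a median of 1.17. This goes against red cell RNA in vehicle mice, which are not the mice of the 5+3 comparison. Less RNA of mature neutrophils, which the sort should also remove, stays open: under 5+3 their markers had a median of -1.74 in mRNA (adjusted p = 0.0214 with an estimated correlation) and -0.97 in footprints (adjusted p = 0.684), beside an effect of the diet on the leukaemia cells, which was not tested apart from it. In vehicle mice, where interferon medians were below 0, their medians of 0.51 in mRNA (quartiles 0.34 to 0.71) and 0.29 in footprints (0.02 to 0.58) go against neutrophil RNA, but the list passed only in mRNA with the preset correlation (adjusted p = 0.0027, against 0.737 in mRNA and 0.851 in footprints with an estimated correlation) and genes of neutrophils went both ways in footprints, with Retnlg at 1.63 and Olfm4 at -1.41.

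Cirbp and Srsf5 footprints were higher in BCAA-free than in amino acid mice under 5+3. Library size does not account for the Cirbp difference. Of the 2 BCAA-free 5+3 libraries within the depth range of the amino acid 5+3 libraries, the lower Cirbp level was 51.6 CPM. The amino acid 5+3 libraries reached at most 9.60 CPM. Srsf5 was not matched on depth. A lower temperature of the mice or samples, to which Cirbp responds, could not be decided: the heat shock list had an mRNA median of -0.33, with adjusted p = 0.438 with an estimated correlation. The diet itself remains open.

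Ribosomal protein genes had more footprints per mRNA in BCAA-free 5+3 than in BCAA-free vehicle mice. Without the 4 mice whose mRNA libraries stood apart the list median was 0.94, against 1.16 with all, and the per-mouse score differed by 0.98 ± 0.298 (SE, n = 6 and 2) against 1.13 ± 0.312 (n = 7 and 5), which cannot decide whether those libraries made the pattern. A shift of short mRNAs stays open: the mRNA median was -0.37 for oxidative phosphorylation but -0.0135 (quartiles -0.287 to 0.324) for mitochondrial ribosomal proteins, against -0.76 for ribosomal proteins, which goes against an equal shift of all 3 lists. A change of the footprints does not account for the whole, since their median was 0.195 (quartiles 0.147 to 0.272), and whether it gave a part stays open (adjusted p = 0.43 with an estimated correlation).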

How the results depend on the processing

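Protein-coding rows only, the 4 mRNA libraries left out and the 2 shallowest footprint libraries left out were chosen after seeing the data, and the other settings were planned. No value of a named gene that passed in the main fit or under the other setting reversed its direction. Changes of sign among values that passed in neither were not counted. Of 3945 gene values with 1 mouse left out 3573 stayed on their side of the threshold, 362 lost the call and 10 gained it, and of 2363 under the other settings 2234 stayed, 99 lost it and 30 gained it. Comparisons are given in the order chemotherapy on the amino acid diet, on the BCAA-free diet, diets in vehicle mice, diets under 5+3 and interaction, and the cause was not tested unless fewer mice or genes entered.

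DESeq2 called 94, 3471, 161, 776 and 169 genes in mRNA, against 13, 1807, 0, 262 and 16 in edgeR. In footprints it called 593 for the diets in vehicle mice against 321. In translational efficiency it called 1, 1735, 18 and 7 for the comparisons other than the diets in vehicle mice. Limma with library weights called 802, 3253, 1, 3510 and 115 in mRNA, 1816 for the interaction in footprints, and 9, 2933, 179 and 2 in translational efficiency, again without the diets in vehicle mice. With no filter on low counts edgeR called 2 and 174 genes in mRNA for the diets in vehicle mice and under 5+3, 659 in footprints for the diets in vehicle mice, and 57, 1601, 113, 146 and 194 in translational efficiency. With only the compared groups in the fit 39 and 701 mRNA genes passed for chemotherapy on the amino acid and on the BCAA-free diet.

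Protein-coding rows only gave 2 mRNA genes for the diets in vehicle mice and 32 for the interaction, 476 footprint genes for the interaction, and 1, 0 and 0 in translational efficiency for chemotherapy on the amino acid diet, the diets under 5+3 and the interaction, where the single calls are pseudogenes that this setting takes out. Without the 4 mRNA libraries 30, 19, 509 and 7 mRNA genes passed for chemotherapy on the amino acid diet, on the BCAA-free diet, the diets under 5+3 and the interaction, and 0 and 0 in translational efficiency for chemotherapy on the BCAA-free diet and the interaction. Without the 2 shallowest footprint libraries 599 footprint genes passed for the diets in vehicle mice and 2102 for the interaction.

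The replicate numbers of the labels name different mice. Of 27 pairs of groups' same-numbered libraries, 6 in footprints and 10 in mRNA had deviations correlated over 0.1. The median r was -0.0154 in footprints and 0.0104 in mRNA, which gives no sign of a pairing. Pairs with different numbers were not set beside them, so a pairing by number is not excluded. With the number as a block mRNA gave 2743, 2, 67 and 6 genes for chemotherapy on the BCAA-free diet, the diets in vehicle mice, the diets under 5+3 and the interaction, and footprints 406 for the interaction, while the block moved no other count by over 1.5 times. Under it Irf8 and Ctsh in mRNA on the amino acid diet, Olfm4 and Pira2 in footprints of vehicle mice, BC100530, Calml4, Gbp2 and Prss34 in mRNA and Bcat2 in footprints under 5+3 did not pass. For the interaction Adss, D16Ertd472e, Fbp1, Hmgb3, Pex7, S100a8, S100a9 and Wfdc21 in mRNA and Bcat2, Evl, Gbp5, Gbp6, H1f0 and Pgrmc1 in footprints did not. Without the mouse block translational efficiency gave 1, 2 and 3 genes for the diets in vehicle mice, the diets under 5+3 and the interaction.

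With 1 mouse left out the mRNA counts ranged over 0 to 10, 546 to 2613, 0 to 1, 101 to 310 and 5 to 29. The footprint counts ranged over 535 to 1162, 2084 to 3740, 163 to 339, 3375 to 4609 and 544 to 1582. Those of translational efficiency ranged over 0 to 0, 4 to 1868, 0 to 0, 0 to 2 and 0 to 1. Simulated 2-fold changes between the diets under 5+3 were recovered for 10.4% of genes in mRNA and 76.1% in footprints, although the mRNA libraries were deeper.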

Other observations

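The gene lists and tests of this part were fixed before the data were examined, and which lists are described here was chosen after their results were seen. Genes of homologous recombination and the Fanconi pathway repair DNA breaks and crosslinks. After 5+3 on the amino acid diet 4 of 25 rose in footprints (9 adjusted over the list alone), with adjusted p = 0.082 with an estimated correlation. Between the diets under 5+3, 14 of 25 were lower and 1 higher on the BCAA-free diet (14 and 1 adjusted over the list alone), led by Rad54b (-1.21), Chek2 (-1.04), Fancg (-0.94) and Atm (-0.78), with adjusted p = 0.19 with an estimated correlation. The interaction had 5 of 25 negative and 1 positive (7 and 1 adjusted over the list alone), with adjusted p = 0.496 with an estimated correlation.

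Of NF-kB and inflammatory cytokine genes 5 of 8 were lower on the BCAA-free diet under 5+3 (5 adjusted over the list alone), including Nfkb2 (-1.91) and Icam1 (-0.68), with adjusted p = 0.162 with an estimated correlation. Of proteasome genes 9 of 31 rose after 5+3 on the amino acid diet (18 adjusted over the list alone), such as Psmc1 (0.43) and Psmd13 (0.39), with adjusted p = 0.0603 with an estimated correlation. In mRNA, enzymes of pyrimidine and purine synthesis had 10 of 24 higher after 5+3 on the BCAA-free diet (19 adjusted over the list alone; adjusted p = 0.263 with an estimated correlation). Ribosome biogenesis had 14 of 46 higher (23 and, lower, 2 adjusted over the list alone; adjusted p = 0.389 with an estimated correlation). Of the MLL-AF9 programme 4 of 21 genes rose and 4 fell in footprints between the diets under 5+3, and the list did not pass (adjusted p = 0.637).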
